A study of Mus musculus with 14 samples.

How the data were processed

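Lung-labelled single-cell suspensions were measured in 14 mouse libraries taken 24 h after surgery, 3 WT sham, 4 WT CLP, 4 KO (Zbp1-/-) sham and 3 KO CLP. Per the labels' protocols, lungs were minced, digested enzymatically, strained and freed of red cells, and libraries were made with a 10x Genomics 3' kit. The deposited values were raw UMI counts per gene and cell barcode; per the submitters' processing notes they were made with Cell Ranger 5.0.0 on the mm10 build. Each deposited count table held 32285 genes and 12 multiplexing tags, which were kept apart from gene counts. Tag UMIs were 8.05% to 26.56% of all UMIs of a library. How barcodes were assigned to libraries was not given in the sources used here. Gene coordinates came from GENCODE annotation of the same build, matched by gene ID for 32158 genes, with 127 unmatched.

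Barcodes with over 20% mitochondrial UMIs were removed (542), which included all 26 with under 200 genes, leaving 20610. Doublets were scored per library with Scrublet, which marked 94 of these (0.46%). At a share this low the caller may not have worked, or barcodes with more than 1 tag may have been removed before deposit, which was not given in the sources used here, so an added alternative removed the 3% of cells with the highest doublet scores in each library. The 20516 kept cells were scaled to 10000 UMIs, logged and reduced to 2000 variable genes and 30 principal components, and Leiden clustering (20 neighbours, resolution 1; scanpy 1.11.5, leidenalg 0.10.2) gave 24 clusters. No integration across libraries was applied. Cell type markers, gene lists, tests and the rule for named genes were fixed before the data were examined. The score and detection thresholds for naming clusters were set afterwards.

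A cluster was called macrophage-like, mesothelial-like or endothelial-like when its highest marker list was of that type with a score of at least 1. All other clusters had Col1a2 in at least 50% of cells and are called collagen-rich, a name for their transcripts and not a cell type: of the 50 fibroblast markers 24 were detected in at least 25% of these cells. Clusters 2, 6, 8, 14 and 23 had 0 markers of fibroblasts or mural cells among their 10 leading genes and 1 or 2 of another type, so the class holds mixed states and its values are not those of a cell type. Cluster 12 was 82.8% KO sham 1, cluster 15 76.1% KO CLP 2 and cluster 16 82.4% from the library labelled WT CLP 4.

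For gene tests, counts were summed per library over the cells of a class with at least 10 cells in at least 3 libraries of each group, which only the collagen-rich clusters met. Sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F-test, all 4 groups in 1 fit without covariates) and Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. Log2 fold changes carry the standard error of the fit, and CPM values their SD over libraries. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom 5.6 or above), so none was treated as a repeat deposit of another; this does not show that libraries were separate animals. Cell counts per class were tested with the same tool and by exact two-sided permutation of shares. Zbp1 was compared as CPM over all kept cells by exact two-sided permutation.

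Of 25 gene lists 22 had at least 5 measured genes and were tested with camera on voom-weighted log2 CPM (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. Haemoglobin, abundant AT2 and club cell, and immunoglobulin transcripts had 1, 1 and 0 measured genes and were left out. Named genes were, per comparison, the 2 largest changes in each direction among genes that passed, did not overlap between groups, reached 50 CPM in the higher group and averaged at least 10% of their level in the class where they were highest, plus up to 4 members of each list that passed and Zbp1. Ribosomal, mitochondrial and unnamed gene models were counted and not named by that rule. Genes with near-identical copies, such as the serum amyloid A family, may share counts.

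The scripts were tested on simulated counts with 200 changed genes. Of 4-fold changes 77%, 72%, 85% and 81% were recovered for WT CLP against WT sham, KO CLP against KO sham, KO CLP against WT CLP and KO sham against WT sham, and 56% for the interaction. For 2-fold changes the shares were 41%, 38%, 39%, 38% and 13%, each over at least 14834 genes, with 3, 4, 7, 9 and 1 false calls. The simulated genes were drawn independently, with no pool effect and no outlying library. These shares therefore check the scripts and are not rates of recovery or error for the real libraries.

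Pools were read from the median count of each foreign tag per barcode: libraries whose log2 backgrounds correlated above 0.9 were put in 1 pool. The labels number the replicates but do not say what a number shares, so pairing was read from the correlation of deviations from the group means between libraries with the same number. Only in KO CLP against KO sham were all 3 pairs over 0.1 (0.14 to 0.5). Alternatives planned before the data were examined were DESeq2 1.42.0, DESeq2-type size factors, no filter on low counts, the replicate number as a block, 30 in place of 10 cells, doublets kept, a mitochondrial limit of 10%, resolution 2, genes under 5% of their level in another class left out, only the 2 groups compared, an estimated correlation and leaving out each library. Added after seeing the data were the 3% doublet removal, leaving out the library labelled WT CLP 4 and the library labelled KO CLP 3, pool C as a term, pool B alone, and fits of macrophage-like and mesothelial-like cells on the CLP libraries.

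Depth limits precision: with 12408548 to 43358257 gene UMIs per library, genes near 1 CPM rest on few counts, and fewest in WT CLP 1. WT CLP libraries were the shallowest per barcode. Genes tested for stray libraries were those of the naming rule used in the text, and Tmsb4x, added after its values were seen. Results of a few genes that the rule named are not reported here. In the tests of exchanged labels and interferon level, the minimums of 5 and 1 CPM were also set after the data were seen.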

Results

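Single-cell RNA sequencing of mouse lung was compared between wild-type (WT) mice and mice lacking Zbp1 (Zbp1-/-, here KO), 24 h after caecal ligation and puncture (CLP) or a sham operation. CLP opens the caecum to the abdominal cavity and is a standard model of sepsis. Zbp1 encodes a sensor of Z-form nucleic acids that can start necroptosis and inflammasome signalling. The labels gave 3 WT sham, 4 WT CLP, 4 KO sham and 3 KO CLP libraries. The 14 libraries held 21152 barcodes, of which 20516 were kept. Gene UMIs (counts of unique RNA molecules) per library ran from 12408548 to 43358257. Median UMIs per barcode were 12799 to 28231 in WT sham, 7973 to 9657 in WT CLP, 12720 to 18423 in KO sham and 10440 to 11671.5 in KO CLP. The labels spoke only of mice, so the p-values measure the spread between libraries, which may be partly technical.

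Most of the captured cells carried abundant fibrillar collagen transcripts. Of the kept cells, 19243 (93.8%) lay in 19 clusters, called collagen-rich here, in which Col1a2, a chain of type I collagen, was detected in 99.48% of cells at a median of 12385 UMIs. Col1a2 was also detected in 75.23% of macrophage-like cells, whose median was 9192 UMIs, so the detection alone includes background; its level was 2600.9 against 774.1 CPM (UMI counts scaled to a common total). Genes higher in collagen-rich than in macrophage-like and endothelial-like cells included Tagln and Acta2 of the contractile cytoskeleton, Timp1, an inhibitor of matrix proteases, and Mgp, a matrix protein. The rest were 864 macrophage-like cells with Lyz2 in 99.54% of them, 339 mesothelial-like cells, and 70 endothelial-like cells with Cdh5, the endothelial cadherin, in 98.57%. The mesothelial marker Msln was detected in only 20.35% of mesothelial-like cells, against 4.75% of collagen-rich cells. Mesothelial-like cells also carried Col1a2 (99.41% of cells, 2247.3 CPM), so this class is less distinct than the others. Abundant AT2 and club cell transcripts were close to nil: the surfactant gene Sftpc reached at most 0.07 CPM in any library and the club cell gene Scgb1a1 at most 1.49 CPM.

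Macrophage-like cells made up 1.47% ± 1.71 of cells in WT sham (SD, n = 3), 5.1% ± 4.31 in WT CLP (n = 4), 4.05% ± 7.67 in KO sham (n = 4) and 6.82% ± 0.56 in KO CLP (n = 3). KO sham 1 held 15.55%, while the other KO sham libraries held 0.08 to 0.31%. Mesothelial-like cells were 2.45% ± 1.25, 1.82% ± 0.31, 0.99% ± 1.4 and 1.87% ± 0.6 in the same order, and collagen-rich cells 96.08% ± 0.8, 92.5% ± 4.8, 94.72% ± 9.41 and 90.76% ± 0.44. Endothelial-like cells were 0 of 4101 in WT sham, which allows a share of up to 0.0732% by counting error alone, over the pooled cells of the 3 libraries, and 0.58% ± 0.34 in WT CLP, 0.24% ± 0.37 in KO sham and 0.55% ± 0.45 in KO CLP. The endothelial-like class was the only 1 of 4 classes to pass between WT CLP and WT sham (adjusted p = 0.0423, edgeR quasi-likelihood test, higher in 4 of 4 CLP libraries, with a mean at least 7.9-fold higher than in WT sham, taken at that limit). That call was lost with trimmed-mean (TMM) scaling over the classes (adjusted p = 0.0577), and when any 1 of 10 libraries was left out, which were all except WT CLP 3, KO sham 1, KO sham 3 and KO CLP 2. The fitted log2 ratio was 6.11 and stayed at 5.74 to 6.38 when a library was left out, although it depends on the prior count because WT sham held no such cell. The exact two-sided permutation test of the shares (adjusted p = 0.229) could not pass for 1 class of 4 with this number of libraries, so it does not bear on the call. No class passed between KO CLP and KO sham, KO CLP and WT CLP, KO sham and WT sham, or in the interaction (0 of 4 each; lowest unadjusted p 0.0359, for endothelial-like cells of KO sham against WT sham). Without KO sham 1 the counts became 4, 0, 2 and 1. Pools of libraries, given below, part WT CLP from WT sham, and without KO sham 1 they part KO CLP from KO sham wholly.

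**Figure D1:**
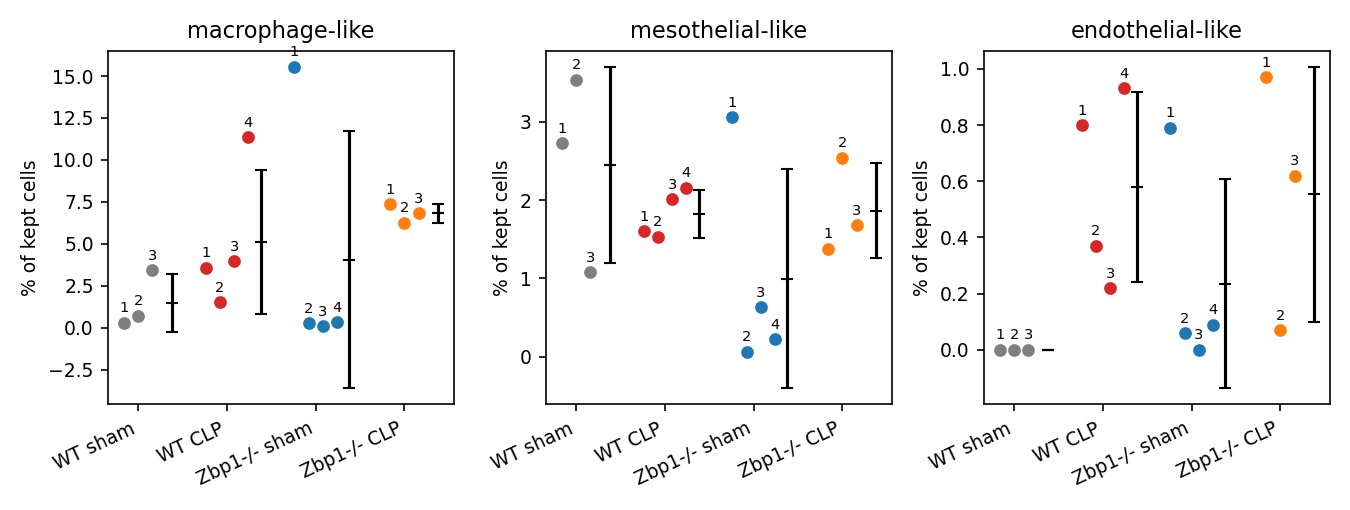
Share of kept cells (%) in the macrophage-like, mesothelial-like and endothelial-like classes, 1 numbered point per library, with the group mean and SD as bars. KO sham 1 stands at 15.55% macrophage-like cells, and the 3 WT sham libraries stand at 0% endothelial-like cells.

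The targeted gene was read first. Zbp1 (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923, minus strand, mm10) stood at 11.4 ± 5.25 CPM in WT sham and 1.15 ± 0.28 CPM in KO sham (SD, n = 3 and 4). The difference, KO minus WT, was -10.25 CPM (exact two-sided permutation p = 0.029, the smallest that 35 splits allow). After CLP it stood at 14.05 ± 8.15 CPM in WT and 5.33 ± 3.9 CPM in KO (n = 4 and 3, exact two-sided permutation p = 0.2, smallest possible 0.029). A library of each CLP group went against its label: the library labelled WT CLP 4 had 1.93 CPM (95% Poisson interval 1.38 to 2.63) beside 17.23 to 19.59 CPM in WT CLP 1 to 3, and the library labelled KO CLP 3 had 9.83 CPM (8.22 to 11.66) beside 3.04 and 3.11 CPM in KO CLP 1 and 2. Intervals cover counting error only. The labels do not state which part of the gene was removed, so 3' tags may lie outside it, and remaining counts in KO libraries cannot show whether a functional transcript was made. All groups below follow the labels.

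**Figure D2:**
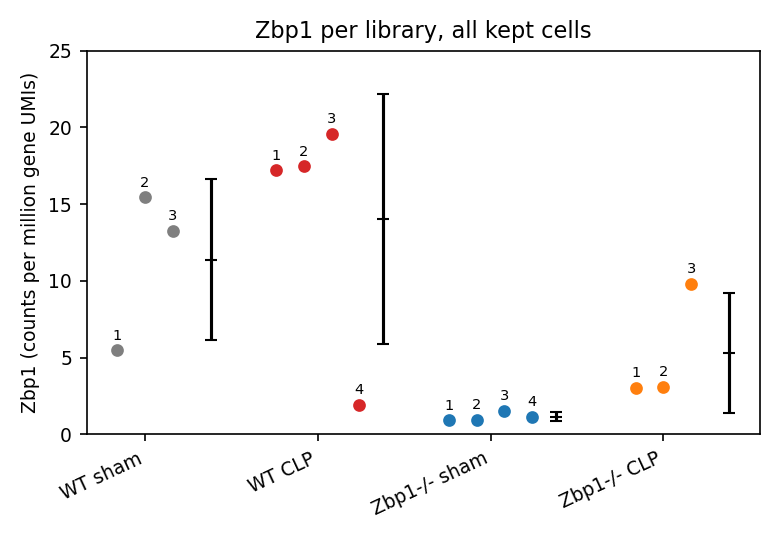
Zbp1 (CPM over all kept cells, linear axis), 1 numbered point per library, with the group mean and SD as bars. The library labelled WT CLP 4 (1.93 CPM) lies among the KO libraries, and the library labelled KO CLP 3 (9.83 CPM) lies above WT sham 1 (5.47 CPM).

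The libraries also carried molecular tags used to pool samples, and the background of foreign tags sorted them into 3 pools. Pool A held WT sham 1 to 3, pool C held KO sham 2 to 4, and pool B held all 7 CLP libraries with KO sham 1. The correlation of tag background was 0.985 to 0.999 over the 34 pairs of libraries within a pool, and -0.206 to 0.694 over the 57 pairs across pools. No cell barcode occurred in both libraries of a pair within a pool, and 32 did across pools. Pool and group therefore cannot be told apart between WT CLP and WT sham or between KO sham and WT sham, and the interaction inherits this, whereas KO CLP and WT CLP lay in 1 pool. This holds for the endothelial-like call too. Every library of pool B held such cells (0.07 to 0.97%), including KO sham 1 at 0.79%. The libraries of pools A and C held 0 to 0.09%.

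**Figure D3:**
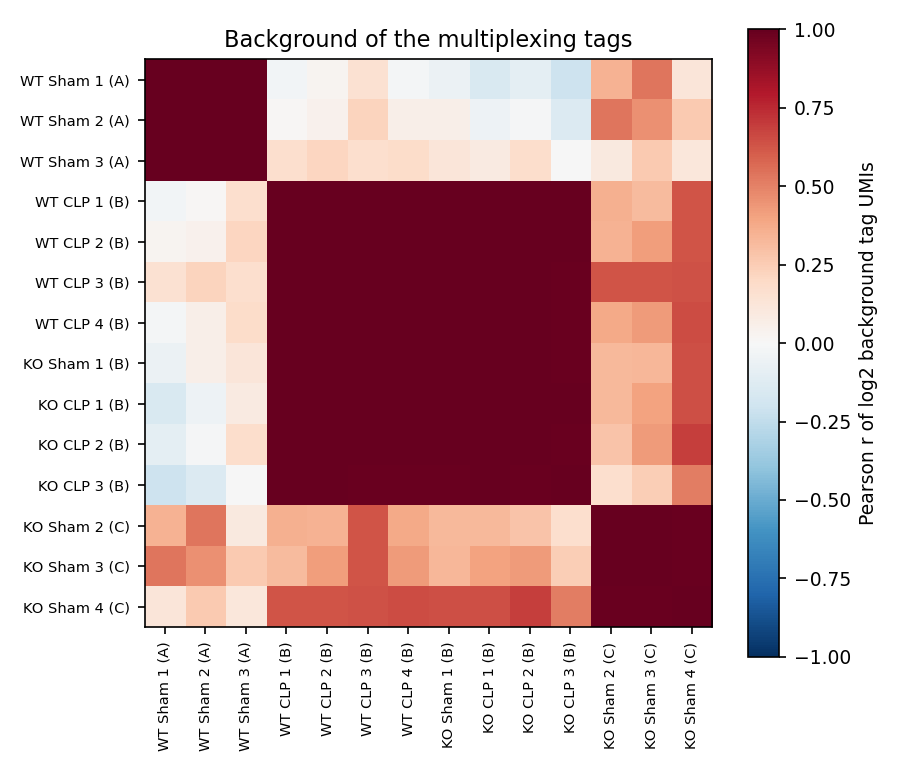
Pearson correlation of the log2 background of the multiplexing tags between libraries, with the pool in parentheses (colour scale from -1 to 1). Pairs within a pool lie at 0.985 or above.

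Over all 4 groups, gene expression was tested only in the collagen-rich clusters, because the other classes had under 3 libraries with 10 cells in at least 1 group. Fits of macrophage-like and mesothelial-like cells on the CLP libraries alone are given under other observations. Different clusters led in each group: cluster 11 held 17.6% of the WT sham cells of this class, cluster 0 34.1% of WT CLP, cluster 1 15.6% of KO sham and cluster 2 19% of KO CLP. All levels below are CPM in these clusters.

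The effect of CLP in WT mice was read from WT CLP against WT sham. Cxcl13 (chromosome 5, 95956951 to 95961068), a chemokine that attracts B cells, rose from 23.3 ± 15.8 to 365 ± 195 CPM (log2 fold change 3.92 ± 0.65, SE). Plcb4, a phospholipase C (chromosome 2, 135659011 to 136014593), rose from 38.4 ± 9.34 to 96.9 ± 30.6 CPM (1.28 ± 0.24). Il1rl1, the receptor of interleukin-33 (chromosome 1, 40429570 to 40465415), fell from 128 ± 168 to 5.04 ± 1.88 CPM (-4.73 ± 0.83), and Tnc, the matrix protein tenascin C (chromosome 4, 63959785 to 64047015), from 548 ± 227 to 146 ± 25.7 CPM (-1.98 ± 0.27). Their adjusted p-values were 0.0422, 0.0476, 0.0432 and 0.0246 (edgeR quasi-likelihood test, Benjamini-Hochberg). The libraries of both groups did not overlap for any of them, which the naming rule required. Of the WT sham mean of Il1rl1, WT sham 1 gave 322 CPM and the other 2 libraries 29.5 and 31.5 CPM. Tmsb4x, the actin-binding thymosin beta-4, was chosen after its values were seen for its low adjusted p (0.00505); it fell from 5370 ± 960 to 2310 ± 265 CPM.

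Of 15071 genes tested, 78 passed, 26 higher and 52 lower after CLP (33.3% higher), with 2646 at an unadjusted p under 0.05. DESeq2 called 875 (48.0% higher), and size factors of the DESeq2 type within edgeR 53 (43.4% higher). The count hung on single libraries: it was 683 without KO sham 1, 235 without the library labelled WT CLP 4 and 175 without WT sham 2; 5 without KO sham 2 or KO CLP 1; 4 without WT sham 3 or KO sham 3; and 2 without WT sham 1, WT CLP 1, WT CLP 2, WT CLP 3, KO sham 4 or the library labelled KO CLP 3. Without both libraries whose Zbp1 went against the label, 110 genes passed (66.4% higher), 46 of them shared with the 78.

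Inflammatory genes stood higher as groups. Of 22 gene lists tested, 13 passed with a preset correlation of 0.01 between genes (camera), and none with an estimated correlation. Chemokines shifted up (19 measured, median log2 fold change 1.70, adjusted p = 3.09e-07; adjusted p = 0.162 with an estimated correlation), with Cxcl13 as the 1 member called and 9 when adjusted over the list alone; Cxcl2, which attracts neutrophils, averaged 2.4 CPM in sham and 17.9 CPM after CLP. Acute-phase and antimicrobial genes shifted up (20 measured, median 1.60, adjusted p = 1.69e-05; adjusted p = 0.455 with an estimated correlation), with 0 members called and 8 adjusted over the list alone. Saa3, a serum amyloid A, averaged 1090 ± 544 CPM in WT sham and 13400 ± 9150 CPM in WT CLP (adjusted p = 0.0952), and Lcn2, the iron-carrier binding lipocalin-2, 164 ± 59.6 and 2030 ± 1410 CPM (adjusted p = 0.0784). These means hid a gap between libraries: Saa3 stood at 12400 to 22600 CPM in WT CLP 1 to 3 and at 1180 CPM in the library labelled WT CLP 4, within the WT sham range of 468 to 1470 CPM. NF-kB and inflammatory cytokine genes shifted up (23 measured, median 0.61, adjusted p = 1.69e-05; adjusted p = 0.455 with an estimated correlation; 0 called, 6 adjusted over the list alone); Nfkbia, the NF-kB inhibitor, averaged 50.4 and 205 CPM, and Tnfaip3, which limits the same pathway, 4.02 and 23.4 CPM.

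**Figure D4:**
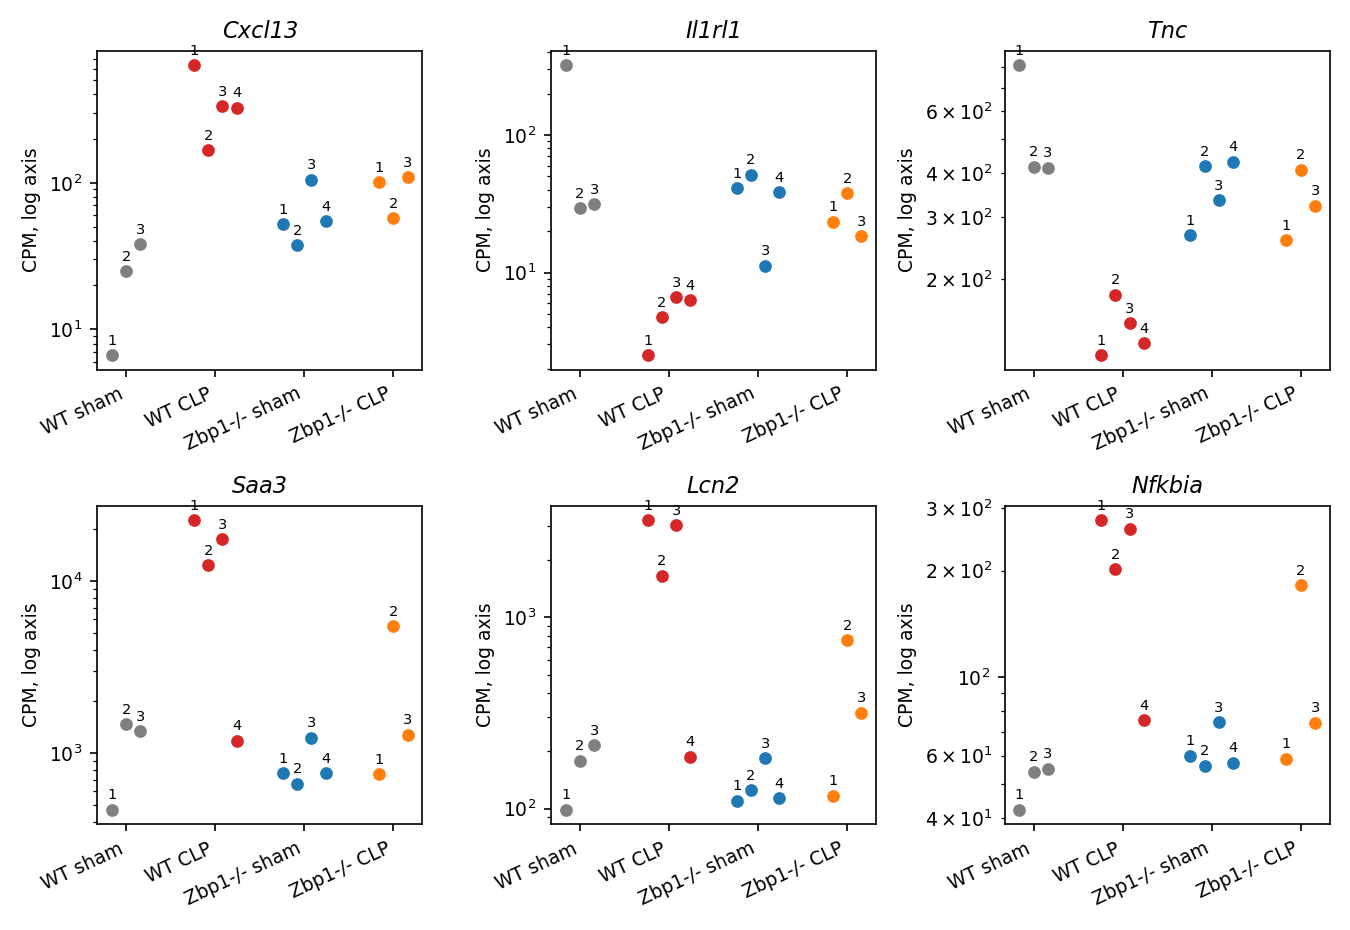
Levels of 6 genes in the collagen-rich clusters (CPM, log axis), 1 numbered point per library. Saa3, Lcn2 and Nfkbia separate WT CLP 1 to 3 from the library labelled WT CLP 4, which lies near the sham libraries for them, while for Cxcl13, Il1rl1 and Tnc it lies with the other WT CLP libraries. The rule that named Cxcl13, Il1rl1 and Tnc required that WT CLP and WT sham libraries did not overlap.

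Interferon-linked lists shifted up too. Type I interferon-stimulated genes (33 measured) had a median of 0.61 (adjusted p = 2.08e-05; adjusted p = 0.488 with an estimated correlation; 0 called, 0 adjusted over the list alone), and the interferon-gamma and MHC class I list (25 measured) 0.59 (adjusted p = 3.4e-05; adjusted p = 0.455 with an estimated correlation; 0 called, 2 adjusted over the list alone). In the second list Gbp5, a guanylate-binding protein, averaged 0.333 CPM in sham and 4.39 CPM after CLP. Immediate early genes shifted up (24 measured, median 0.46, adjusted p = 0.0216; adjusted p = 0.525 with an estimated correlation; 0 called, 0 adjusted over the list alone), with Fosb at 45.1 and 122 CPM. Leukocyte lists did as well: neutrophil activation (19 measured, median 1.29, adjusted p = 3.42e-05; adjusted p = 0.224 with an estimated correlation; 0 called, 6 adjusted over the list alone), abundant neutrophil transcripts (8 measured, median 1.11, adjusted p = 0.0071; adjusted p = 0.406 with an estimated correlation; 0 called, 2 adjusted over the list alone) and alveolar macrophage identity (22 measured, median 0.27, adjusted p = 0.00361; adjusted p = 0.224 with an estimated correlation; 1 called, 3 adjusted over the list alone). The called member was Trem2, a lipid receptor of macrophages, at 0.642 and 1.97 CPM, and the macrophage-like share of the same libraries was 1.47% and 5.1%. The neutrophil gene Retnlg reached at most 0.07 CPM in any library. Of 16 neutrophil markers, 1 was detected in at least 25% of collagen-rich cells, so the neutrophil lists do not show that neutrophils were captured.

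Matrix and metabolic lists shifted down. Extracellular matrix genes (34 measured, median -0.55, adjusted p = 0.000508; adjusted p = 0.455 with an estimated correlation) had 2 called members, Tnc and Thbs1, and 5 adjusted over the list alone; Thbs1, thrombospondin 1, fell from 1280 ± 682 to 405 ± 92 CPM (adjusted p = 0.0435). Genes of oxidative phosphorylation (52 measured, median -0.15, adjusted p = 3.42e-05; adjusted p = 0.455 with an estimated correlation; 0 called, 3 adjusted over the list alone) included Uqcrq, a subunit of respiratory complex III, at 425 ± 55.6 and 285 ± 38.9 CPM. Hypoxia and glycolysis genes (31 measured, median -0.43, adjusted p = 0.00276; adjusted p = 0.525 with an estimated correlation) included the hexokinase Hk2 at 76.7 and 45.7 CPM, and heat shock and folding genes (24 measured) had a median of -0.24 (adjusted p = 0.00453; adjusted p = 0.406 with an estimated correlation); both lists had 0 called members and 0 adjusted over the list alone. The sham mean of Hk2 rested on WT sham 1 (126 CPM). WT sham 2 and 3 stood at 54.7 and 49.2 CPM, and WT CLP at 39.1 to 50.2 CPM. In the direction of the shift, the median of the hypoxia list was -0.33 in WT sham 1, 0.22 and 0.15 in WT sham 2 and 3, and 0.2 to 0.43 in WT CLP (log2, relative to WT sham). The other 9 lists did not pass: MHC class II (adjusted p = 0.709, with a median of -0.05 against an upward test), cell death effectors (0.28), metallothionein and glucocorticoid response (0.42), endothelial activation (0.4), endothelial identity (0.351), surfactant and lipid genes (0.709), T and NK cell activation (0.303), naive lymphocyte genes (0.432) and cell cycle (0.252).

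In KO mice no single gene passed between CLP and sham: 0 of 15071 with edgeR, 3029 at an unadjusted p under 0.05, and 1082 with DESeq2. Of the 22 lists 7 passed with the preset correlation, and none with an estimated one. Up were type I interferon-stimulated genes (median 0.71, adjusted p = 0.00046; adjusted p = 0.69 with an estimated correlation), the interferon-gamma list (0.55, adjusted p = 0.0027; adjusted p = 0.69 with an estimated correlation), chemokines (0.73, adjusted p = 0.0014; adjusted p = 0.514 with an estimated correlation) and neutrophil activation (0.57, adjusted p = 0.00301; adjusted p = 0.514 with an estimated correlation). Adjusted over the list alone, 0, 4, 2 and 0 of their members passed. Down were hypoxia and glycolysis (-0.46, adjusted p = 0.00046; adjusted p = 0.69 with an estimated correlation), heat shock and folding (-0.26, adjusted p = 0.00046; adjusted p = 0.514 with an estimated correlation) and matrix genes (-0.56, adjusted p = 0.00376; adjusted p = 0.69 with an estimated correlation). Adjusted over the list alone, 0, 5 and 5 of their members passed as lower, and 3 matrix genes as higher. The other 15 lists did not pass (adjusted p from 0.0566 to 0.907).

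Among these KO genes, Rsad2, an antiviral interferon-stimulated gene, averaged 0.991 ± 0.481 CPM in sham and 6.05 ± 6.5 CPM after CLP, with KO CLP 2 at 13.5 CPM and the other 2 libraries at 1.69 and 2.95 CPM. Cxcl10, an interferon-induced chemokine, stood at 21.6 CPM in KO CLP 2 and at 0.406 and 4.42 CPM in KO CLP 1 and the library labelled KO CLP 3. Timp1 averaged 2380 ± 957 CPM in sham and 886 ± 116 CPM after CLP (adjusted p = 0.0806), and the co-chaperone Bag3 63.5 ± 6.4 and 46.8 ± 1.71 CPM (0.0526). KO sham 2 to 4 stood at 2080 to 3340 CPM for Timp1 and 64.5 to 68.3 CPM for Bag3. KO sham 1 lay nearer to KO CLP, at 1180 and 54.2 CPM. The KO CLP libraries stood at 753 to 969 and 45.1 to 48.6 CPM. KO sham 2 to 4 formed pool C; with pool C as a term, which leaves KO sham 1 as the only sham library of pool B, 115 genes passed. With that term 6 lists passed, and only the 2 interferon lists, still up, were shared with the 7; NF-kB, acute-phase and metallothionein lists passed as higher and cell cycle as lower instead. The count was 2674 without KO sham 1, 632 without WT sham 1 and 20 with DESeq2-type size factors, and 11 lists passed without KO CLP 1. Without KO sham 1 the comparison sets pool B wholly against pool C, so the 2674 genes cannot be told apart from pool. Without KO CLP 2 or without KO sham 1, 5 lists passed, and neither interferon list did. The median level of type I interferon-stimulated genes (log2, relative to the mean of all libraries) was 1.19 in KO CLP 2, -0.19 in KO CLP 1, -0.07 in the library labelled KO CLP 3, -1.26 in KO sham 1 and -0.24 to 0.08 in KO sham 2 to 4.

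The effect of the genotype after CLP was read from KO CLP against WT CLP, within pool B. Acute-phase genes were lower as a group in KO (median -1.68, adjusted p = 3.66e-08; adjusted p = 0.378 with an estimated correlation; 0 called, 9 adjusted over the list alone). Saa3 averaged 2500 ± 2590 CPM in KO CLP and 13400 ± 9150 CPM in WT CLP, and Lcn2 399 ± 330 and 2030 ± 1410 CPM. The KO means rested on KO CLP 2: Lcn2 stood at 762 CPM there and at 117 and 318 CPM in KO CLP 1 and the library labelled KO CLP 3. In KO CLP 2 Saa3 stood at 5480 CPM, and in KO CLP 1 and the library labelled KO CLP 3 at 752 and 1280 CPM, near the KO sham values of 664 to 1230 CPM. Saa1, another serum amyloid, averaged 0.577 and 5.76 CPM, and Ch25h, which makes 25-hydroxycholesterol, 18.8 ± 9.27 and 62.7 ± 22.7 CPM (adjusted p = 0.472 each). The WT means rested on WT CLP 1 to 3. For Saa3, Lcn2 and Saa1 these stood at 12400 to 22600, 1650 to 3230 and 3.77 to 11.7 CPM. The library labelled WT CLP 4 stood at 1180, 187 and 1.0 CPM. For Ch25h it stood at 37.4 CPM, between WT CLP 1 to 3 (49.7 to 84.1 CPM) and KO CLP (9.55 to 28.1 CPM).

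The lists of NF-kB genes (median -0.49, adjusted p = 3.81e-06), chemokines (-0.56, adjusted p = 0.00348), endothelial activation (-0.41, adjusted p = 0.0107) and abundant neutrophil transcripts (-0.70, adjusted p = 0.0404) were lower in KO, each with an adjusted p = 0.378 with an estimated correlation. Neutrophil activation (-0.43, adjusted p = 0.0404) and immediate early genes (-0.39, adjusted p = 0.00176) were lower with an adjusted p = 0.413 with an estimated correlation. Oxidative phosphorylation (0.18, adjusted p = 4.35e-11) and heat shock genes (0.15, adjusted p = 0.0132) were higher, each with an adjusted p = 0.378 with an estimated correlation, and cell cycle genes (0.83, adjusted p = 3.26e-06) with an adjusted p = 0.594 with an estimated correlation. These 9 lists had 0 called members and 0 adjusted over the list alone. Cdh5 was detected in 0.44% of collagen-rich cells, so the endothelial activation list does not show a change in endothelial cells. Relb, an NF-kB subunit, averaged 17.4 ± 4.64 CPM in KO and 33.0 ± 10.5 CPM in WT, and Cxcl13 89.2 ± 27.8 and 365 ± 195 CPM; for Cxcl13 the library labelled WT CLP 4 stood at 325 CPM, with WT CLP 1 to 3 at 167 to 633 CPM and KO CLP at 57.4 to 109 CPM. Tubb5, a beta-tubulin, averaged 687 ± 162 and 410 ± 136 CPM. For Relb and Tubb5 the library labelled WT CLP 4 stood within the KO CLP range. It had 19.6 and 606 CPM, and KO CLP had 12.9 to 22.2 and 501 to 797 CPM. WT CLP 1 to 3 had 31.6 to 44.8 and 297 to 393 CPM. The other 12 lists did not pass (adjusted p from 0.0851 to 0.938).

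No single gene passed between KO CLP and WT CLP: 0 of 15071 with edgeR, 1453 at an unadjusted p under 0.05, and 60 with DESeq2. Without the library labelled WT CLP 4 the count was 12, and without both libraries whose Zbp1 went against the label it was 1. It was also 1 with only the 8 libraries of pool B and 1 with only the 2 groups in the fit. The 10 lists, 7 lower and 3 higher in KO, became 6 without KO CLP 1, of which 2 were lower (NF-kB and acute-phase genes) and 4 higher. Of the 6, 5 were shared with the 10, and the other was type I interferon-stimulated genes, higher in KO.

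Between unchallenged genotypes, KO sham against WT sham, 3 of 15071 genes passed, all higher in KO and named after their values were seen. They were the mitochondrial transcripts mt-Nd2 (1402 ± 34.7 against 797 ± 28.3 CPM, adjusted p = 0.0144) and mt-Cytb (4022 ± 95.3 against 2798 ± 111 CPM, adjusted p = 0.016), and Gm5148, a predicted gene model (0.68 ± 0.1 against 0.05 ± 0.01 CPM, adjusted p = 0.0144). The median mitochondrial share of UMIs per barcode was 2.54 to 3.18% in the WT sham and 3.57 to 3.93% in the KO sham libraries. In WT CLP, at 3.96 to 4.25%, mt-Nd2 stood at 1201 ± 165 CPM and mt-Cytb at 3953 ± 246 CPM. Heat shock genes shifted up (median 0.31, adjusted p = 0.00103; adjusted p = 0.711 with an estimated correlation; 0 called, 1 adjusted over the list alone), with the endoplasmic reticulum chaperone Hspa5 at 597 ± 74.5 against 433 ± 8.26 CPM. Oxidative phosphorylation genes shifted up by a median of 0.11 (adjusted p = 0.0169; adjusted p = 0.968 with an estimated correlation; 0 called, 0 adjusted over the list alone). Another 20 lists did not pass (adjusted p from 0.185 to 0.957). The heat shock shift went with pool C. In the direction of the WT CLP shift (down), its list median was -0.25 to -0.22 in KO sham 2 to 4 (log2, relative to WT sham). KO sham 1, of pool B, stood at -0.04, within the WT sham range of -0.04 to 0.06. Hspa5 was 499 CPM in KO sham 1, 585 to 671 CPM in KO sham 2 to 4 and 424 to 439 CPM in WT sham.

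At an unadjusted p under 0.05 there were 1875 genes in this comparison, and DESeq2 called 341. The count of 3 was 752 without WT sham 1 and 916 without KO sham 1, and 0 without WT sham 2, WT sham 3, KO sham 2 or KO sham 4; it was 0 with no filter on low counts and with only the 2 groups in the fit. The 2 lists became 5 without WT sham 1 or KO sham 1, and 1 without WT sham 2 or KO sham 2.

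Whether the effect of CLP differed between genotypes was tested as an interaction, with both libraries whose Zbp1 went against the label kept in their labelled groups. No gene passed (0 of 15071 with edgeR, 533 at an unadjusted p under 0.05, 15 with DESeq2), including Cxcl13 (interaction -3.55 ± 0.83, adjusted p = 1.0). Of the 22 lists 8 passed. The CLP effect was smaller or more negative in KO for NF-kB genes (median -0.59, adjusted p = 8.69e-05), acute-phase genes (-1.33, adjusted p = 0.0028), chemokines (-0.60, adjusted p = 0.0347), endothelial activation (-0.47, adjusted p = 0.0347) and immediate early genes (-0.45, adjusted p = 0.0028). For oxidative phosphorylation the interaction was positive (0.08, adjusted p = 0.0133), with median CLP effects of -0.15 in WT and -0.04 in KO; each of these 6 lists had an adjusted p = 0.798 with an estimated correlation. T and NK cell activation (-0.37, adjusted p = 0.0347; adjusted p = 0.59 with an estimated correlation) and cell cycle genes (0.47, adjusted p = 0.0347; adjusted p = 0.898 with an estimated correlation) completed the 8. None of their members was called, and 1 chemokine and 0 of the rest passed when adjusted over the list alone. In collagen-rich cells, Cdh5 was detected in 0.44%. Of 28 T cell and 23 NK cell markers, 1 and 0 were detected in at least 25% of these cells. The endothelial and T and NK lists therefore do not show a change in endothelial, T or NK cells. The other 14 lists did not pass (adjusted p from 0.215 to 0.878).

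The interaction lists rested on few libraries: 0 passed without KO CLP 1, 3 without WT sham 1, WT CLP 1 or WT CLP 3, and 5 without WT sham 3 or KO sham 1, and the gene count was 2 without KO sham 1. Across genes, which are not independent replicates, the CLP effects of both genotypes had Pearson r = 0.62 and Spearman rho = 0.61 (15071 genes, no shared libraries, jackknife SE of r over libraries 0.14). Both effects set CLP libraries of pool B against sham libraries that, except KO sham 1, lay in other pools, so a difference between pools enters both. With no filter on low counts r was 0.23.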

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

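The tests of pool, exchanged labels over the whole genome and on genes of the CLP response, cell states, interferon level, RNA release and growth in culture described here were chosen after the results were seen; the tests of other splits, the genes near Zbp1 and the rules that picked out single libraries were set before.

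The first pattern is the sorting of libraries into 3 pools by multiplexing tags, a signal in data that no comparison used, with a correlation of tag background of at least 0.985 within a pool. For WT CLP against WT sham, a shift common to the libraries of pool B is argued against only for interferon-gamma, acute-phase and abundant neutrophil genes. In each, at least 3 of the 8 pool B libraries lay within or beyond the WT sham range. The only WT library among them was the library labelled WT CLP 4, whose label is in doubt. The median of acute-phase genes (log2, relative to WT sham) was -1.11 to 0.28 in KO sham 1, KO CLP 1 and the libraries labelled KO CLP 3 and WT CLP 4. It was 1.51 to 2.13 in WT CLP 1 to 3. Within KO, KO sham 1 and KO CLP 1 lay within or under the range of pool C for these lists, for acute-phase genes at -1.11 and -0.9 against -0.44 to 0.21. KO CLP 2 and the library labelled KO CLP 3 lay above that range, for acute-phase genes at 0.65 and 0.28. This sets pool B against pool C and not against pool A. For the other lists that passed, and for the 78 genes, where 1 of the 8 pool B libraries lay within or beyond the WT sham range, a shift common to pool B cannot be told apart from CLP. For chemokines no pool B library did so, and KO sham 1 stood at 0.4 (WT sham at most 0.06). Heat shock genes went with pool in KO. In the direction of the WT CLP shift, KO sham 2 to 4 stood at -0.25 to -0.22 and the KO libraries of pool B at -0.04 or above. WT CLP itself differed by only 0.14 for them. For oxidative phosphorylation it differed by 0.06, and its libraries (-0.05 to 0.22) overlapped WT sham (-0.03 to 0.03). For genotype among sham libraries and the interaction pool stays untested, since all WT sham libraries and no others lie in pool A. The heat shock shift among sham libraries was nevertheless seen only in pool C, with KO sham 1 at -0.04 inside the WT sham range (-0.04 to 0.06). Among KO sham libraries, the term for pool C against pool B called 3843 genes, although pool B then rests on KO sham 1 alone, and for KO CLP against KO sham 115 genes passed with the pool term and 0 without it, so no kept share could be computed. Genotype after CLP was compared within pool B, with pool held constant.

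The second pattern is Zbp1 in the library labelled WT CLP 4, at 1.93 CPM far below the other WT CLP libraries (17.2 to 19.6 CPM), with the library labelled KO CLP 3 high at 9.83 CPM. Its mix of clusters argues against cell states as the whole cause: its level was 0.19 of that expected at this mix from the other WT libraries, a ratio that was 0.54 to 1.26 in those 6 libraries. For a weak interferon response the bounds set did not decide. Its median level of interferon-stimulated genes, 0.04 (log2, relative to the mean of all libraries), lay below WT CLP 1 to 3 (0.36 to 0.43) and above WT sham (-0.81 to -0.02). These sham libraries, with lower interferon levels, still had 5.47 to 15.45 CPM of Zbp1, which argues against a weak interferon response as the whole cause. An exchange of both labels stays open: of 3 genes that separated the other 6 WT from the other 6 KO libraries at least 2-fold, 1 put both libraries on the opposite side and 1 on the labelled side, and of 7 genes within 20 Mb of Zbp1 that separated them by any size, 2 and 2 did, too divided to decide, while of 34 genes called between WT CLP and WT sham without both libraries that separated WT CLP 1 to 3 from KO CLP 1 and 2 at least 2-fold, 0 put both on the opposite side, 5 on the labelled side, and 29 put only the library labelled WT CLP 4 on the opposite side, which a weak CLP response may also give. A wrong label of 1 library, a mixed sample or incomplete removal of the gene may also apply and was not tested apart.

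The third pattern is the scarcity of other lung cell types. Sftpc, Sftpb, Scgb1a1, Hbb-bs and Hba-a1 reached at most 1.49 CPM in any library. This argues against loss of such cells after they had released their RNA into the captured suspension. RNA released before straining and red cell removal need not remain there, so an earlier loss stays open. Growth of the cells in culture before capture is a candidate explanation that cannot be told apart from selective digestion: of the lung fibroblast genes Inmt, Npnt and Tcf21, detected in 2.44%, 20.85% and 5.69% of collagen-rich cells (median 12385 UMIs) and as background in 0.58%, 4.86% and 1.27% of macrophage-like cells (9192 UMIs), only Npnt clearly exceeded the bound of 5% set for that explanation and none reached the 50% set against it, while the proliferation gene Mki67 stood at 13.22 to 124.02 CPM. The labels describe no culture. No biological explanation was tested.

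KO sham 1 differed from the other KO sham libraries in several measures. It held 80.6% collagen-rich cells (others 99.3 to 99.6%), 15.6% macrophage-like cells (0.08 to 0.31%) and 0.79% endothelial-like cells (0 to 0.09%). In its collagen-rich cells Acod1 stood at 0.42 CPM (others 0.0305 to 0.0535) and Uqcrq at 353 CPM (491 to 502). It is also the only sham library in pool B.

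Other single libraries apart from their group were WT CLP 1 for Acod1 (1.52 CPM, others 0.729 to 0.837), KO sham 3 for Rsad2 (1.71 CPM, others 0.72 to 0.767), WT CLP 3 for Cxcl10 (5.07 CPM, others 1.64 to 2.18), and the library labelled WT CLP 4 for Nlrc5 (1.62 CPM, others 0.895 to 0.972) and Hspa8 (1280 CPM, others 948 to 999). In all, 11 of 88 tests picked out a library, where chance picks about 1 in 20. WT sham and KO CLP, with 3 libraries each, were not tested in this way.

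Differences between genotypes in the CLP effect passed for 8 gene lists at the preset correlation, by the interaction term: NF-kB genes (adjusted p = 8.69e-05), acute-phase genes (0.0028), immediate early genes (0.0028), oxidative phosphorylation (0.0133), and chemokines, endothelial activation, T and NK cell activation and cell cycle (0.0347 each). None passed with an estimated correlation. All were tested in collagen-rich cells, so a list named for another cell type does not show a change in that type.

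Other splits of the same libraries show whether chance can be excluded. For genes of WT CLP against WT sham it cannot: 2 of 35 splits gave at least the real 78, and the highest other split gave 121, with the library labelled WT CLP 4 joined to WT sham. Nor can it for KO sham against WT sham (real 3), where 6 of 35 did and the highest other gave 2756. Where the real count was 0, every split gives as many by construction (35 of 35 for KO CLP against KO sham, 35 of 35 for KO CLP against WT CLP, 40 of 40 drawn for the interaction), so these counts of splits say nothing about chance. Their highest other splits gave 2879, 152 and 36 genes. The 2879 came from setting KO sham 2 to 4 apart, which is pool C; the term for that pool called 3843 among KO sham libraries, while the real comparison gave 115 with that term. The 152 came from joining the library labelled WT CLP 4 to KO CLP 1 and the library labelled KO CLP 3. Splits that call many times the real count point to a structure of the samples other than the groups.

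For gene lists chance cannot be excluded in any of the 5 comparisons: 5 of 35 splits gave at least the real 13 (highest other 13) for WT CLP against WT sham, 19 of 35 at least 7 (13) for KO CLP against KO sham, 17 of 35 at least 10 (15) for KO CLP against WT CLP, 34 of 35 at least 2 (9) for KO sham against WT sham, and 20 of 40 at least 8 (13) for the interaction. For KO CLP against KO sham, where the replicate numbers paired the libraries, the 8 splits that part all 3 pairs are too few for a share under 0.05 (real 7 lists, highest other 8).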

How the results depend on the processing

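The alternatives on pool, on the libraries whose Zbp1 went against the label and on the 3% doublet removal were chosen after seeing the data; the rest were planned. Of 394 alternative values of the main results, 317 kept their direction and side of the threshold, or for a count stayed within 1.5 times. For the named genes, 3804 of 4010 alternative values did, 78 lost and 128 gained the call, and 0 reversed. Resolution 2, keeping doublets and the 3% removal moved no gene count by over 1.5 times, and a minimum of 30 cells removed no library from any test.

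For genes of WT CLP against WT sham, where 78 passed, DESeq2 gave 875, no filter 3, the 10% mitochondrial limit 42 and only the 2 groups compared 33, of which 7 were shared and 26 higher (78.8%, against 33.3% of the 78). KO CLP against KO sham (0) gave 1082 with DESeq2, 20 with DESeq2-type size factors and 115 with pool C as a term, where 6 lists passed in place of 7 and 2 were shared, both of interferon genes. For KO CLP against WT CLP (0) the values were 60 with DESeq2, and 1 without both libraries whose Zbp1 went against the label, 1 in pool B alone and 1 with only the 2 groups. In KO sham against WT sham (3) DESeq2 gave 341, no filter 0 and only the 2 groups 0, and the interaction (0) gave 15 with DESeq2. Lists that passed fell from 13, 7, 10, 2 and 8 to 0 in every comparison with an estimated correlation, and the interaction gave 5 lists with no filter. The correlation of CLP effects, 0.62, was 0.23 with no filter and 0.83 over the 78 genes called in WT, a set chosen on 1 of its axes. The endothelial-like call (1) became 0 with TMM over the classes and 0 without both libraries whose Zbp1 went against the label, while its fitted log2 ratio of 6.11 was 6.15 and 5.77; the exact permutation test could not pass for 1 class of 4. Except where fewer libraries or more genes entered a test, the cause was not tested.

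Leaving out each library gave 2 to 683 genes for WT CLP against WT sham (683 without KO sham 1), 0 to 2674 for KO CLP against KO sham (2674 without KO sham 1), 0 to 12 for KO CLP against WT CLP (12 without the library labelled WT CLP 4), 0 to 916 for KO sham against WT sham (916 without KO sham 1) and 0 to 2 for the interaction (2 without KO sham 1). The 2674 set pool B wholly against pool C, so CLP and pool cannot be told apart there. Lists ranged over 12 to 14, 5 to 11, 6 to 12, 1 to 5 and 0 to 11; the 6, without KO CLP 1, held 2 lower lists in place of 7. Cell classes ranged over 0 to 1, 0 to 4, 0 to 0, 0 to 2 and 0 to 1, the correlation of CLP effects over 0.5 to 0.64, and the KO minus WT level of Zbp1 over -13.21 to -8.22 CPM in sham and -12.77 to -6.88 CPM in CLP (-15.02 CPM without both libraries whose Zbp1 went against the label).

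The replicate numbers of the labels did not pair the libraries in WT CLP against WT sham (1 of 3 pairs over a correlation of 0.1), KO CLP against WT CLP (1 of 3) or KO sham against WT sham (2 of 3). In KO CLP against KO sham all 3 pairs were over 0.1, and with the block its counts stayed at 0 genes and 7 lists, the same 7. Over the 19 pairs with the same number, deviations from the group means correlated at -0.46 to 0.58, with 11 over 0.1, and 8 of 14 libraries correlated best with their own number. With the replicate number as a block, 3 genes passed for WT CLP against WT sham and 0 for KO sham against WT sham, where 1 list passed; it changed no other count by over 1.5 times.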

Other observations

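The fits of macrophage-like and mesothelial-like cells, the segment test and the choice of genes here were made after the results were seen.

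Macrophage-like cells could be compared within the CLP libraries alone (7 libraries, 609 cells). No gene passed between KO CLP and WT CLP (0 of 8477 with edgeR, 245 at an unadjusted p under 0.05; DESeq2 was not run), and 1 passed without the library labelled WT CLP 4 and the library labelled KO CLP 3. Of 22 lists 3 were lower in KO: NF-kB genes (adjusted p = 0.0305), acute-phase genes (0.0106) and oxidative phosphorylation (2.3e-07), each with an adjusted p = 0.967 with an estimated correlation. In collagen-rich cells oxidative phosphorylation stood higher in KO (median 0.18); the difference between the classes was not tested.

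In mesothelial-like cells (7 libraries, 190 cells) 0 of 6508 genes passed with edgeR, 385 at an unadjusted p under 0.05 (DESeq2 was not run), and 48 without both libraries whose Zbp1 went against the label. Cxcl1, which attracts neutrophils, averaged 68.3 CPM in KO and 186 CPM in WT (adjusted p = 0.171), and Ankrd1 101 and 27 CPM (0.171). Of 19 lists 11 passed with the preset correlation and none with an estimated one, among them chemokines lower in KO (adjusted p = 3.42e-06; adjusted p = 0.147 with an estimated correlation) and hypoxia and glycolysis higher (2.66e-07; adjusted p = 0.332 with an estimated correlation).

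Csf3, the granulocyte growth factor, stood high in the CLP libraries where Saa3 did: WT CLP 1 to 3 stood at 61.7 to 76.9 CPM, KO CLP 2 at 41.8 CPM, the library labelled WT CLP 4 at 6.31 CPM, KO CLP 1 at 3.86 CPM and the library labelled KO CLP 3 at 5.24 CPM, with 3.45 to 4.83 CPM in sham libraries. Isg15, an interferon-induced protein, stood at 179 CPM in KO CLP 2 and at 7.56 to 36.6 CPM in the other 13 libraries.

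A chromosome segment carried along with the Zbp1 allele was tested as a hypothesis for differences between KO CLP and WT CLP, on unadjusted p-values because no gene passed after adjustment. Of 263 tested genes within 20 Mb of Zbp1, 11 (4.2%) had an unadjusted p under 0.05, against 1442 of 14807 elsewhere (9.7%), an odds ratio of 0.4 (95% interval 0.2 to 0.74, Fisher's exact two-sided p = 0.00143). These groups hold both libraries whose Zbp1 went against the label, and a wrong genotype there would hide genes linked to the allele. Without them it was 27 of 267 (10.1%) against 2043 of 15076 (13.6%), an odds ratio of 0.72 (95% interval 0.46 to 1.07, Fisher's exact two-sided p = 0.124). Both upper limits lay under the 2 set as bound, which argues against a 2-fold excess of such genes near Zbp1.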
